A study of Microcystis aeruginosa with 24 samples.

How the data were processed

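RNA sequencing of axenic *Microcystis aeruginosa* PCC 7806 was analysed from the deposited table of gene counts. The culture grew at 22 °C in 13 h light and 11 h dark, in mineral medium with 20 mM NaHCO3 and 1% CO2, at an optical density at 750 nm of 0.6 to 0.7. One preculture was split into flasks A, B and C, whose volume the labels give in differing ways, and 150 mL was drawn from each flask at each of 8 times, so that the 24 libraries are repeated samples of the same 3 flasks. The labels give t3_D as 12 am, read as noon from the order of the times. Per the labels, RNA was extracted with Trizol and columns, ribosomal RNA was removed, stranded libraries were made and the samples were randomised before processing. The values are raw counts per gene as deposited, and the authors made them from aligned reads. The submitters' processing notes name Bowtie 1.2.2, featureCounts 1.4.6-p3, Subread, R 3.3.1 and DESeq2 1.12.3, with no role or order. The genome build, the annotation, the strand setting and the treatment of reads that align to several places were not given in the sources used here.

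The table held 5554 genes, of which 1036 carried a symbol (903 distinct symbols), 41 were transfer RNAs and 7 other RNAs, and 32 had 0 counts in all libraries. The transfer and other RNAs took 1.06% to 3.30% of the counts per library. In 268 genes the counts were identical in all libraries to those of at least 1 other gene; these formed 104 groups of up to 15 genes and held 1.90% of all counts, and 240 of them were tested (4.65% of tested genes). Near-identical genes, such as MICAP_3279 and MICAP_1792, were not named among the results. Total counts per library ran from 4149170 to 10915414. A count of 0 allows up to 3 counts, which corresponds to 0.197 to 2.05 TMM-scaled CPM across libraries and covers counting error only. Between replicates the variation exceeded counting error, with a chi-square per degree of freedom of 11.1 to 414 over 24 pairs of libraries of the same time.

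Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. All 24 libraries entered 1 edgeR quasi-likelihood fit with the time point as the only factor, TMM factors and the filterByExpr filter (minimum count 10, minimum total count 15), which left 5157 genes. The fit had 16 residual degrees of freedom and a common biological coefficient of variation of 0.267. The p were adjusted by Benjamini and Hochberg over all genes tested in each comparison, and a gene passed at an adjusted p under 0.05. Beside that, the number changed at least 2-fold (log2 change of at least 1) was counted. The comparisons were the change across the 8 times, the mean of the 4 light times against the mean of the 4 dark times, t2_D against t1_N (lights on), t6_N against t5_D (lights off), t8_N against t1_N (same clock hour) and 5 steps between adjacent times within a phase. Opposite calls at the light transitions were counted against the overlap of independent lists of the same sizes, and for each changed gene the time with the highest mean log2 CPM (prior count 2) was recorded. Levels are TMM-scaled CPM with SD over libraries, and log2 changes carry the SE of the fit.

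Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 tested members, adjusted over the lists, and again with an estimated correlation and with fry. They were fixed before the data were examined, from textbook physiology: photosystem I, photosystem II, phycobilisome, chlorophyll synthesis, cytochrome b6f and mobile carriers, ATP synthase, NDH-1 complex, carbon fixation and concentration, glycogen synthesis, glycogen breakdown and oxidative pentose phosphate pathway, terminal oxidases, circadian clock, sigma factors, RNA polymerase core, ribosomal proteins, aminoacyl-tRNA synthetases, nitrogen uptake and assimilation, phosphate uptake, iron homeostasis, gas vesicles, microcystin cluster, other peptide and polyketide natural products, type IV pili, chaperones and proteases, oxidative stress defence, cell division, DNA replication and fatty acid synthesis. Members were matched by symbol only, as the table gives no products. Lists for photoprotection, transposases, CRISPR-Cas and RNA genes matched 0 genes and toxin-antitoxin systems 2, so these 5 were not tested.

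Genes were named by a rule fixed before the data were examined, which covered only the 1031 of 5157 tested genes with a symbol. For each of the 4 main comparisons it took the 5 largest rises and 5 largest falls among genes past the test with a mean log2 CPM of at least 4 and the same direction in all 3 flasks, the 2 genes of each list with the smallest p, and a fixed set (kai, sasA, mcy, psbA, Rubisco, cpcA, zwf, gnd, glgP, glgC and gvpA genes). For the steps within a phase it took the 2 largest rises and 2 largest falls. The genes mcaA and mcaD and the genes named for flask C were chosen after their values were seen.

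The alternatives planned before the data were examined were DESeq2 size factors, upper-quartile factors and library totals alone in the edgeR fit, no filter on low counts, a filter of at least 10 counts in every library of a group, removal of the RNA genes and the 10 most abundant genes, the flask as a term, only the 6 libraries compared, DESeq2 with and without the flask as a term, the estimated correlation, dark samples without t1_N, and leaving out each flask and each library. Keeping 1 of each group of genes with identical counts, the list tests for the 5 steps and the list counts without t1_N and without flask C were added after the data were seen. The flask letter pairs the libraries, since per the labels the same flask was sampled at each time. The fit was fixed without the flask as a term because the labels give no design formula, and the fit with it was an alternative. In a check on the residuals of the time means, libraries of the same flask at different times correlated at 0.206 on average over 84 pairs, 44 of them over 0.1, and libraries of different flasks at -0.0984 over 168 pairs. The correlation within a flask varied with time. It was 0.568 to 0.739 between t5_D and t6_N, 0.00276 to 0.0870 between t1_N and t2_D, and 0.0017 to 0.0598 between t1_N and t8_N. A flask term that is constant over time does not model this.

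Other splits of the libraries into groups were tested, 10 for each pair of times and 100 for the comparisons over all times. The fit was tested on simulated data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. At lights on 4.48%, 35.8% and 89.4% of these were found, with 9 false calls among 101, and between light and dark 58.2%, 98.5% and 100%, with 10 false calls among 201. At lights off 7.46%, 35.8% and 89.4% were found, and between t8_N and t1_N 8.96%, 35.8% and 80.3%. Where 20 abundant genes were raised 5-fold in simulated data, TMM factors gave 0 calls among 5085 unchanged genes and library totals alone 4870. In the real data the shift at lights on was spread over many more genes. The simulation therefore does not show which scaling was right there. The simulated data with genes changed 1.5-fold to 4-fold also held 1 changed list, and none of 20 unchanged lists passed in any comparison. Genes were drawn there independently and without a flask effect. The list result therefore does not cover correlation among genes or within a flask. All libraries were drawn from 1 mean composition with 1 spread per gene. In the real data the median count per gene averaged 21.7 at t1_N and 230 at t2_D. The shares found and the false calls therefore hold for the simulated setting only. Libraries were also thinned to the lowest total in 5 draws.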

Results

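Transcript levels of *Microcystis aeruginosa* PCC 7806, a bloom-forming cyanobacterium that makes the toxin microcystin, were measured by stranded RNA sequencing over 24 h of a cycle of 13 h light and 11 h dark. The same 3 flasks (A, B and C), split from 1 preculture, were sampled at 8 times, which gave 24 libraries and n = 3 per time. Sample t1_N was taken in the dark 1 h before lights on, and t2_D, t3_D, t4_D and t5_D were taken 1, 4, 8 and 12 h after lights on. Samples t6_N, t7_N and t8_N came from the following dark phase, 14, 18 and 23 h after lights on. The count table held 5554 genes, of which 5157 were tested and 1031 of those carried a gene symbol. Genes are named here by symbol and MICAP identifier, since no genome coordinates were given in the sources used here. Total counts per library ran from 4149170 to 10915414, with a median of 8096761.

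The t1_N libraries stood apart in composition. Their 20 most abundant genes took 54.8% ± 1.28 (SD, n = 3) of all counts, against 35.2% ± 3.02 at t2_D. The mean TMM factor, which corrects library totals for composition, was 0.371 at t1_N and 1.77 at t2_D. Flask C also stood apart. Its t6_N library correlated at 0.136 with the mean profile of the other flasks at that time, against 0.539 for flask A and 0.697 for flask B. In the light its t4_D library matched t3_D best (0.827, and 0.770 with its own time) and its t5_D library t4_D (0.705, and 0.655), while t4_D of flask A matched t5_D best (0.752, and 0.701). Its t7_N and t8_N libraries correlated better with the t1_N profile than with the profile of their own time, by 0.171 on average, while the same difference was -0.201 in flask A and -0.184 in flask B. The first principal component held 64.3% of the variance and the next 13.0%.

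**Figure D1:**
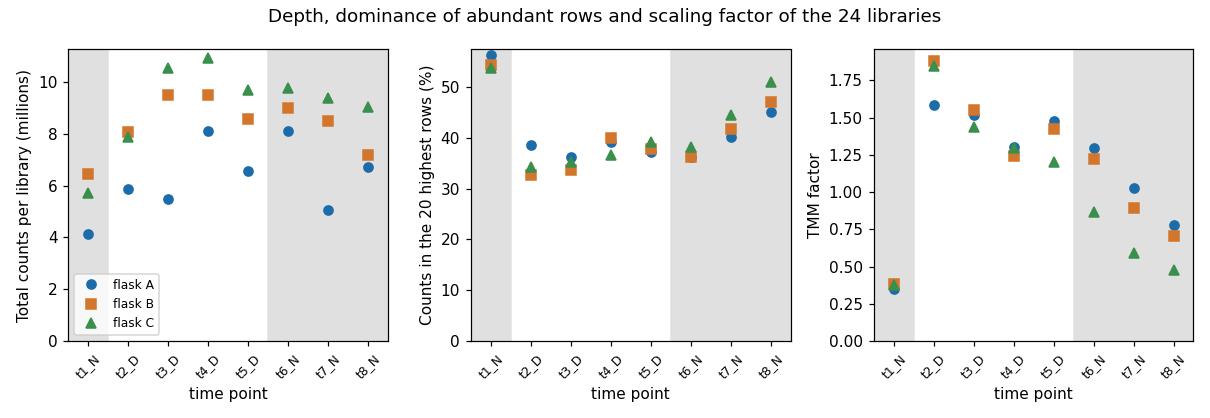
Total counts (left), percent of counts in the 20 most abundant genes (middle) and TMM factor (right) for each of the 24 libraries by time point, with flask A as circles, B as squares and C as triangles, and dark times shaded grey. Total counts ran from 4149170 to 10915414, and the TMM factors were lowest at t1_N (mean 0.371) and highest at t2_D (mean 1.77).

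**Figure D2:**
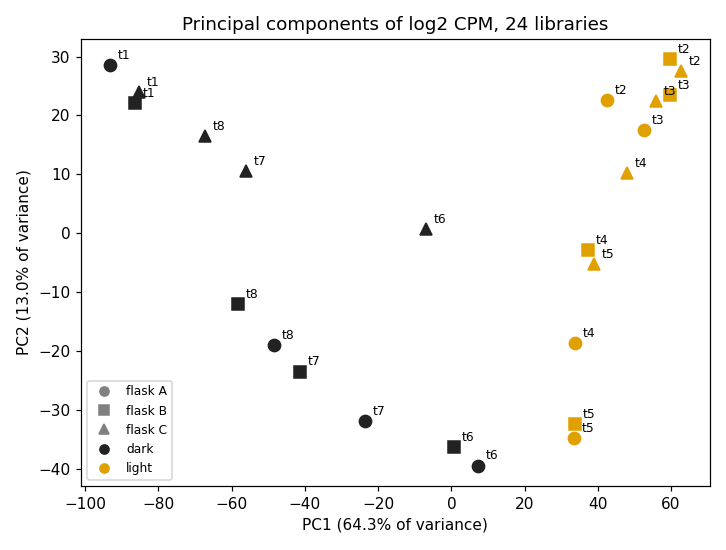
Principal components of log2 CPM, one point per library, with PC1 (64.3% of variance) on the horizontal axis, PC2 (13.0%) on the vertical axis, colour for light or dark and shape for flask. Flask C lay at -56.0 and 10.6 at t7_N and at -67.3 and 16.5 at t8_N, on the side of the 3 t1_N libraries.

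The first question was which transcripts varied over the 24 h and when they were highest. Of the 5157 genes tested, 4237 (82.2%) changed across the 8 times, with a median range of 2.12 on the log2 scale, and 920 did not pass. Levels were highest at t2_D for 1303 of the changed genes (30.8%) and at t1_N for 1072 (25.3%), so the extremes lay on either side of lights on. With library totals alone, without TMM factors, 2366 of these genes peaked at t2_D and 106 at t1_N, and with flask C left out 842 of the genes then called peaked at t2_D. Of the 11 photosystem I genes, 10 were highest at t1_N, as were 29 of the 49 ribosomal protein genes, of which 22 in all passed the test across the 8 times. Of the 9 gas vesicle genes, which encode the buoyancy organelle, 6 were highest at t3_D and 3 at t4_D. The microcystin genes were highest later, 3 at t3_D, 4 at t4_D and 2 at t6_N.

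The clock genes differed among copies. kaiC (MICAP_0803), encoding the core clock ATPase, rose from 3.96 ± 1.17 CPM (mean ± SD, n = 3) at t1_N to 74.7 ± 8.42 at t2_D and was back at 9.68 ± 1.81 at t6_N. Its neighbour kaiB (MICAP_0802) went from 1.00 ± 0.877 to 17.4 ± 1.38 and 3.16 ± 0.241 CPM at the same times. In flask A at t1_N that gene had 0 counts, where the depth allows up to 2.05 CPM on this scale, so its level at t1_N lay near the limit of counting. A further kaiB copy (MICAP_4307) had another course, with a fall at lights on that turned to a rise of 0.19 on the log2 scale with library totals alone: 107 ± 11.4 CPM at t1_N, 25.6 ± 3.95 at t2_D and 255 ± 37.5 at t6_N. kaiA (MICAP_0801) stayed between 79.6 ± 4.26 CPM at t5_D and 113 ± 7.02 CPM at t2_D. That course depends on the scaling, with mean TMM factors of 0.371 at t1_N and 1.77 at t2_D. With library totals alone its change from t1_N to t8_N turned to a rise of 0.72 on the log2 scale.

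**Figure D3:**
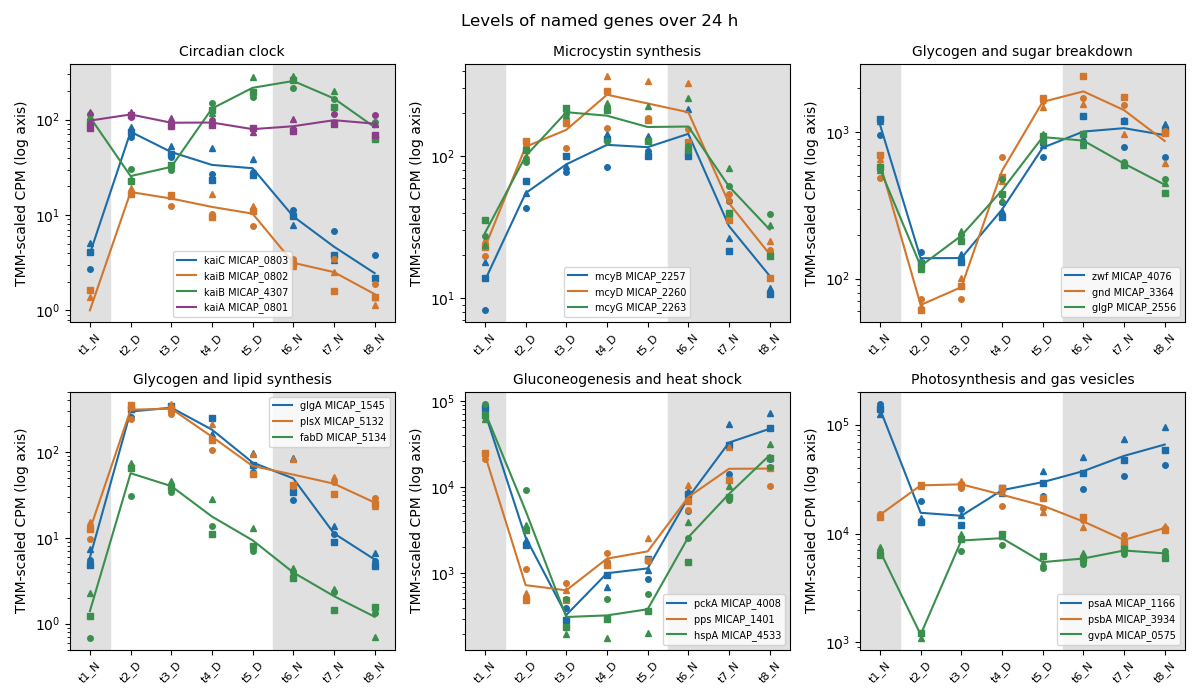
TMM-scaled CPM on a log axis against time point for clock, microcystin, glycogen and sugar breakdown, glycogen and lipid synthesis, gluconeogenesis and heat shock, and photosynthesis and gas vesicle genes, with points for flasks (circle A, square B, triangle C), lines for means and dark times in grey. A library at 0 is not drawn on the log axis (kaiB MICAP_0802 in flask A at t1_N); kaiC (MICAP_0803) had its highest mean, 74.7 CPM, at t2_D.

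Light samples were compared with dark samples to find which functions belonged to the day and which to the night. Levels of ndhD (MICAP_4902), encoding a subunit of the NDH-1 complex, were 3.89 ± 0.12 higher in the light on the log2 scale (SE, n = 12 and 12 libraries), and those of the glycogen synthase gene glgA (MICAP_1545) were 4.04 ± 0.19 higher. The gene prk (MICAP_4802), for phosphoribulokinase of the Calvin cycle, rose by 2.59 ± 0.22. The largest fall was that of pckA (MICAP_4008), encoding phosphoenolpyruvate carboxykinase, with -4.93 ± 0.25. Small heat shock gene hspA (MICAP_4533) fell by 4.37 ± 0.28 and pps (MICAP_1401), for phosphoenolpyruvate synthase, had -3.81 ± 0.24. Each of these went the same way in all 3 flasks, which the naming rule required of the largest rises and falls. Adjusted p (edgeR) ran from 1.4e-15 for ndhD to 5.7e-10 for prk.

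Genes of glycogen breakdown and the oxidative pentose phosphate pathway, which make reducing power from stored sugar, were mostly lower on average in the light: 7 of 9 fell, 1 rose and 1 did not pass, although 3 of the 9 were highest at t5_D, the last light sample. The median was -1.97 and the list passed the test (adjusted p = 0.000132), but not with an estimated correlation (adjusted p = 0.422 with an estimated correlation). Among them zwf (MICAP_4076) had -2.01 ± 0.12, gnd (MICAP_3364) -2.04 ± 0.13 and glgX (MICAP_4993) -2.33 ± 0.11. All 9 microcystin genes rose (median 1.55, adjusted p = 0.0148, and adjusted p = 0.855 with an estimated correlation), for example mcyD (MICAP_2260) by 2.00 ± 0.18 and mcyJ (MICAP_2266) by 2.19 ± 0.18. In fatty acid synthesis 11 of 14 genes rose and 1 fell (median 1.18), led by fabD (MICAP_5134) with 3.66 ± 0.22 and plsX (MICAP_5132) with 2.60 ± 0.16. That list passed at an adjusted p of 0.0393, and at adjusted p = 0.855 with an estimated correlation it did not. It also missed the threshold without the RNA genes and the 10 most abundant genes (adjusted p = 0.0507), and without t6_N of flask A (adjusted p = 0.0573), t7_N of flask A (0.0671) or t8_N of flask A (0.0625), and its adjusted p ranged from 0.000419 to 0.855 over all alternatives.

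All 11 photosystem I genes were lower on average in the light (median -1.04, but 0.14 with library totals alone), among them psaA (MICAP_1166) with -1.68 ± 0.18. Of the 11, 10 were highest at t1_N, and at lights off the list did not pass (camera, adjusted p = 0.769). The difference may therefore rest on t1_N, and the list test was not run without that time. The list had an adjusted p of 0.0393 (adjusted p = 0.855 with an estimated correlation), and did not pass without the RNA genes and the 10 most abundant genes (adjusted p = 0.127, range over alternatives 0.0116 to 0.855). Of 27 chaperone and protease genes 17 fell and 6 rose (median -1.04, but 0.08 with library totals alone), at an adjusted p of 0.0121 (adjusted p = 0.855 with an estimated correlation). The fallen chaperone genes included clpB (MICAP_5196) with -4.23 ± 0.28 and dnaK (MICAP_2538) with -1.93 ± 0.11. Phosphate uptake had 9 rises and 1 fall among 12 genes and NDH-1 had 10 rises and 3 falls among 14, with adjusted p of 0.0628 and 0.0942. With the flask as a term in the fit these were 0.0434 and 0.0236. Over their alternatives the first ran from 0.00635 to 0.855 and the second from 0.000806 to 0.8999. Of the 16 genes for other natural products 8 rose and 6 fell (adjusted p = 0.125), with no test run per cluster; among them was mcnG (MICAP_3368) of the cyanopeptolin cluster at 3.85 ± 0.17, while the microcyclamide genes mcaA to mcaE each fell, from -1.24 for mcaA (MICAP_4423) to -1.53 for mcaD (MICAP_4426). Of 7 clock genes 4 rose and 2 fell (adjusted p = 0.334), with kaiC (MICAP_0803) at 3.23 ± 0.17 and kaiB (MICAP_4307) at -1.01 ± 0.11, which was 0.09 with library totals alone. The gas vesicle list split, with 5 rises and 3 falls among 9 genes (adjusted p = 0.577), the falls being the 3 gvpA copies, from -0.37 (MICAP_0577) to -0.49 (MICAP_0578), which became 0.73 and 0.60 with library totals alone. Adjusted over the list alone, the number of changed members differed in 2 of the 28 lists and by at most 1 gene.

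In all, 4060 of 5157 genes differed between light and dark (edgeR), 2267 higher and 1793 lower in the light, and 2302 of them at least 2-fold. Without the t1_N libraries 3802 genes passed, 1899 higher and 1903 lower in the light, so the excess of higher genes was gone. Without flask C 3963 passed. Library totals alone gave 4434 genes, 3948 higher and 486 lower, so the share higher in the light was 55.8% with TMM factors and 89.0% without, and 624 genes called in both fits turned direction. Over all genes tested, that scaling moved the median log2 difference by 1.09 for this comparison, by 2.25 at lights on, by 0.81 between t8_N and t1_N, by -0.29 at lights off, and by -0.24, -0.23, 0.09, -0.43 and -0.35 for the 5 steps within a phase, in order of time. Since each flask was sampled 8 times, the residuals of a flask were not independent.

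At lights on (t2_D against t1_N, n = 3 and 3 libraries) the changes were larger. Level of glgA (MICAP_1545) rose by 5.64 ± 0.42 on the log2 scale, from 5.91 ± 1.31 to 296 ± 36.7 CPM, and ndhD (MICAP_4902) rose by 5.71 ± 0.27. fabD (MICAP_5134) rose by 5.26 ± 0.51 and plsX (MICAP_5132), which acts in phospholipid synthesis, by 4.62 ± 0.36. Among the genes that the naming rule allowed, the falls were led by pps (MICAP_1401) with -5.01 ± 0.50, phbB (MICAP_2588) with -5.00 ± 0.28 and pckA (MICAP_4008) with -4.80 ± 0.50. ctaA (MICAP_5410), for the heme A that cytochrome oxidase needs, fell by 4.78 ± 0.60, and the oxidase subunit genes coxA (MICAP_5408) and ctaC (MICAP_5409) had -3.19 ± 0.31 and -3.29 ± 0.35. All of these moved the same way in the 3 flasks, which the naming rule required of the largest rises and falls. Adjusted p (edgeR) ran from 5.7e-12 for ndhD to 4.6e-07 for ctaA.

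Of the 9 glycogen breakdown and oxidative pentose phosphate genes 8 fell at lights on (median -2.88, adjusted p = 2.91e-06, and adjusted p = 0.22 with an estimated correlation), such as zwf (MICAP_4076) with -3.03 ± 0.25. All 11 photosystem I genes fell (median -3.17, adjusted p = 1.38e-05, and adjusted p = 0.804 with an estimated correlation), such as psaK (MICAP_5094) with -3.64 ± 0.37. Of 10 genes of cytochrome b6f and mobile carriers 8 fell, among them the plastocyanin gene petE (MICAP_0074) with -2.90 ± 0.31; the median was -1.89 but 0.36 with library totals alone. That list passed at an adjusted p of 0.00446 (adjusted p = 0.804 with an estimated correlation). With the flask as a term, 5 lists passed in place of 3, adding fatty acid synthesis, with 10 rises and 1 fall among 14 genes (adjusted p = 0.0857, and 0.00684 with the term), and the phycobilisome, with 10 falls and 2 rises among 12 genes (0.0857, and 0.0412 with the term). Over their alternatives these adjusted p ran from 0.00255 to 0.804 and from 0.000778 to 0.804. Carbon fixation split, with 7 falls and 4 rises among 13 genes (median -1.75, but 0.50 with library totals alone, adjusted p = 0.722). The falls there included the Rubisco gene cbbL (MICAP_4036), with -3.21 ± 0.90, and the rises icfA (MICAP_4856), for carbonic anhydrase, with 3.42 ± 0.54. Of the 9 microcystin genes 7 rose and 1 fell (adjusted p = 0.247), mcyA (MICAP_2258) rising by 2.02 ± 0.30. The changes of mcyC (MICAP_2256) and mcyF (MICAP_2262) were negative, but turned to 1.86 and 0.39 with library totals alone. Adjusted over the list alone, 5 of the 28 lists gave another number of changed genes, by at most 2.

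The test passed 3744 genes at lights on, 2203 higher and 1541 lower, and 3143 of them changed at least 2-fold. Library totals alone gave 4545 genes, 4275 higher and 270 lower, or 94.1% higher in place of 58.8%, and turned the direction of 703 genes called in both fits. Without flask B 2949 genes passed, and with the flask as a term 3922.

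At lights off (t6_N against t5_D, n = 3 and 3) heat shock genes and pckA were higher 1 h into the dark than 1 h before it. hspA (MICAP_4174) rose by 2.96 ± 0.48, clpB (MICAP_5196), a chaperone that dissolves protein aggregates, by 3.14 ± 0.54 and pckA (MICAP_4008) by 2.73 ± 0.46. ndhD (MICAP_4902) had -2.12 ± 0.23, chlG (MICAP_3387), for chlorophyll synthase, -2.10 ± 0.41, kaiC (MICAP_0803) -1.67 ± 0.29 and kaiB (MICAP_0802) -1.71 ± 0.29. The nitrogen regulator gene glnB (MICAP_5301), at a low level, fell by 3.45 ± 0.43. All went the same way in the 3 flasks, which the naming rule required of the largest rises and falls. Adjusted p (edgeR) ran from 2.9e-05 for ndhD to 0.0027 for chlG. Of the chaperone and protease genes 9 of 27 rose and 1 fell, and 10 changed adjusted over the list alone. Their median was 0.44 and their list passed at an adjusted p of 0.00284, but at adjusted p = 0.883 with an estimated correlation it did not. None of the 49 ribosomal protein genes passed singly; their median was 0.52 at an adjusted p of 0.109, and with the flask as a term the list passed at 0.0371 (range over alternatives 0.000351 to 0.991). The number of lists past the test, 1 with all libraries, was 2 without flask A, B or C, t5_D of flask A or C, t6_N of flask A or B, or t7_N or t8_N of flask C, and 5 without t6_N of flask C. No microcystin, photosystem I or gas vesicle gene passed, except mcyJ (MICAP_2266) with the flask as a term (-0.68), whereas the pilin genes pilA (MICAP_4133 and MICAP_4134) rose by 1.29 ± 0.27 and 1.16 ± 0.26. In 8 of the 28 lists the number of changed genes differed when adjusted over the list alone, by at most 1.

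At lights off 690 genes passed, 335 higher and 355 lower, with 371 at least 2-fold; 1383 had an unadjusted p under 0.05. Upper-quartile factors gave 663, with 192 higher and 471 lower (29.0% higher against 48.6%), and library totals alone gave 497, with 114 higher and 383 lower (22.9% higher). The count was lowest without flask B, at 3 genes, against 413 without A and 375 without C. That omission leaves A and C, which differed most, with a chi-square per degree of freedom of 283 at t5_D and 414 at t6_N. For B and C it was 261 and 372, and for A and B 41.3 and 51.9. The loss therefore does not show that the changes lay in flask B. With only the 6 libraries compared 180 genes passed. Of the 31 named genes that passed, 2 (ndhD MICAP_4902 and glnB MICAP_5301) held without each flask in turn, and 17 without any single library. Without flask B, clpB, hspA and pckA had adjusted p of 0.0761, 0.0761 and 0.108 (ranges over alternatives 9.91e-09 to 0.0761, 9.66e-10 to 0.0761 and 9.89e-09 to 0.108), and kaiC, kaiB and chlG had 0.108, 0.112 and 0.125 (5.19e-07 to 0.108, 2.6e-08 to 0.112 and 1.56e-05 to 0.125). Both pilA genes had 0.208 and 0.221 (3.29e-06 to 0.208 and 9.71e-06 to 0.221). Among single libraries, leaving out t5_D of flask A, B or C gave 445, 456 or 359 genes, and leaving out t6_N of flask B or C gave 417 or 442.

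Most genes that passed at lights off had moved the other way at lights on. Of the 355 genes lower at lights off, 338 (95.2%) had been higher at lights on, where independent lists would share 151.7, and of the 335 genes higher at lights off 307 (91.6%) had been lower, against 100.1. The 645 genes with opposite calls included ndhD (MICAP_4902), kaiC (MICAP_0803) and kaiB (MICAP_0802) in the one direction and pckA (MICAP_4008), clpB (MICAP_5196) and both pilA genes in the other. Only 11 genes were higher at both transitions and 8 lower at both. Across the 5157 genes, which are not independent replicates, the log2 changes at the 2 transitions had r = -0.74 and rho = -0.75. Leaving out flask B left 3 opposite calls, A 398 and C 349. Leaving out t5_D of flask A, B or C left 426, 425 or 347, and t6_N of flask B or C 399 or 416.

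The samples t8_N and t1_N, 24 h apart at the same clock hour, show how far the cycle returned to its start. Levels of sepF (MICAP_5176), a cell division gene, were 1.52 ± 0.31 higher at t8_N, those of the peptide deformylase gene def (MICAP_1124) 1.60 ± 0.31 higher and those of a further kaiC copy (MICAP_5291) 1.60 ± 0.43 higher, with adjusted p of 0.0092, 0.0083 and 0.027. Thioredoxin gene trxA (MICAP_2631) had -2.50 ± 0.60, hspA (MICAP_4533) -1.66 ± 0.51 and psaJ (MICAP_4495) -1.53 ± 0.39, with adjusted p of 0.02, 0.047 and 0.023. The main clock copies kaiC (MICAP_0803) and kaiB (MICAP_0802) had -0.70 ± 0.46 and 0.40 ± 0.59, and no microcystin gene passed. Of the 11 photosystem I genes 6 fell and 9 changed adjusted over the list alone (median -1.41, adjusted p = 1.11e-08, and adjusted p = 0.598 with an estimated correlation). The phycobilisome had 2 falls among 12 genes, 3 changed adjusted over the list alone (median -0.99, adjusted p = 1.06e-05), and ATP synthase 1 fall among 10 (median -1.06, adjusted p = 6.57e-05), each at adjusted p = 0.598 with an estimated correlation. No ribosomal protein gene passed singly, with a median of -0.63 over 49 genes (adjusted p = 1.16e-06). Photosystem II, with 1 fall among 17 genes, had a median of -0.73 but 0.03 with library totals alone, cytochrome b6f and mobile carriers -0.53 but 0.24, and NDH-1 -0.44 but 0.29. Their adjusted p were 2.92e-05, 0.00123 and 0.0307. Carbon fixation (median -0.97, adjusted p = 0.00217) and the RNA polymerase core (median -0.79, adjusted p = 0.00474) also passed without any gene passing singly. With the flask as a term rplM (MICAP_4946, -1.74), rpsP (MICAP_0049, 0.67), ccmM (MICAP_4034, -1.57), rpoB (MICAP_2715, -0.88) and rpoC (MICAP_2714, -1.11) of these lists passed, and 10 lists passed, the other natural products being the one added. Each of these 9 lists had adjusted p = 0.598 with an estimated correlation, and none passed with fry, where 7 of the 28 lists had an unadjusted p under 0.05. The NDH-1 call was lost without flask B (adjusted p = 0.101), t1_N of flask C (0.0972), t8_N of flask A (0.0821) or t8_N of flask B (0.091), and ranged from 0.00164 to 0.598 over alternatives. DNA replication, with 1 rise among 12 genes, had 5 changed adjusted over the list alone (adjusted p = 0.166).

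Between t8_N and t1_N 422 genes passed, 314 higher and 108 lower (74.4% higher), with 263 at least 2-fold and 1365 at an unadjusted p under 0.05. DESeq2 size factors in the same fit gave 329 genes, 204 higher and 125 lower (62.0% higher), and library totals alone 2622, of which 2599 were higher (99.1%). With the flask as a term 791 genes passed. With only the 6 libraries compared 1 gene passed, lower at t8_N, so the 422 calls depend on a spread estimated with the other times. The count depended on the flasks: edgeR passed 0 genes without A (768 at an unadjusted p under 0.05) and 0 without B (570), but 1305 without flask C, the flask whose t8_N library was nearest the t1_N profile; DESeq2 passed 542 with all libraries, 269 higher and 273 lower, and 1042 with the flask as a term, 399 higher and 643 lower, so which direction held more genes depended on the tool. Single t1_N libraries of flask A, B or C left out gave 78, 179 or 133 genes, and single t8_N libraries 75, 58 or 894. All 23 named genes that passed were lost without flask A and without flask B and held without C, while def and sepF alone held under every single library left out.

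Within the light phase, gas vesicle genes rose between t2_D and t3_D. Of 9 genes 7 rose, and all 9 changed adjusted over the list alone, with a median of 1.11 (adjusted p = 5.06e-20), a call that held with an estimated correlation (adjusted p = 0.00419 with an estimated correlation). The structural gene gvpA (MICAP_0575) went from 6899 ± 634 CPM at t1_N to 1181 ± 68.5 at t2_D and 8629.9 ± 1572 at t3_D, so that on this scale most of its rise followed a dip. Of the 9 microcystin genes 6 rose, also 6 adjusted over the list alone (median 1.38, adjusted p = 1.1e-10, and adjusted p = 0.188 with an estimated correlation), the largest rise being mcyC (MICAP_2256) with 3.20 ± 0.48. The change of mcyC at lights on had been negative with TMM factors but 1.86 with library totals alone. Part of the photosynthesis genes rose over this step: 10 of 17 in photosystem II, 5 of 11 in photosystem I, 7 of 12 in the phycobilisome, 4 of 10 in cytochrome b6f, 3 of 10 in ATP synthase and 6 of 12 in chlorophyll synthesis, with medians from 1.04 (cytochrome b6f) to 1.57 (ATP synthase). Adjusted over the list alone these were 11, 7, 7, 6, 5 and 6 genes. Their adjusted p were 1.71e-06 for each of the first 3 and then 2.08e-06, 4.75e-06 and 8.79e-05, and adjusted p = 0.273 to 0.31 with an estimated correlation. The antenna gene apcA (MICAP_3921) rose by 2.96 ± 0.65. Carbon fixation passed as a list (median 1.02, adjusted p = 0.00101, and adjusted p = 0.591 with an estimated correlation) with no gene past the test singly. Of 27 chaperone and protease genes 7 fell, 8 changed adjusted over the list alone (median -0.35, adjusted p = 0.000154, and adjusted p = 0.228 with an estimated correlation), with hspA (MICAP_4533) at -4.09 ± 0.56 and hspA (MICAP_4174) at -3.16 ± 0.48.

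From t3_D to t4_D and again to t5_D, the glycogen breakdown and oxidative pentose phosphate genes rose hours before dark. At the first step 8 of 9 rose (median 1.10, adjusted p = 1.59e-17, and adjusted p = 0.00315 with an estimated correlation) and at the second 6 of 9 (median 1.29, adjusted p = 1.43e-24, and adjusted p = 0.000375 with an estimated correlation); all 9 changed at both steps adjusted over the list alone. Without flask B no gene at all passed singly in edgeR from t4_D to t5_D (141 at an unadjusted p under 0.05), so there the 6 calls were lost and the list call alone held. Level of gnd (MICAP_3364) went from 87.4 ± 13.9 CPM at t3_D to 544 ± 116 at t4_D and 1612 ± 120.1 at t5_D. Genes of terminal respiration moved alongside: ctaA (MICAP_5410) rose by 4.12 ± 0.58 and coxE (MICAP_5411) by 3.72 ± 0.56 from t3_D to t4_D. Of the 3 terminal oxidase genes 2 rose at that step and 3 changed adjusted over the list alone (median 2.01, adjusted p = 2.4e-06, and adjusted p = 0.0535 with an estimated correlation). The other lists past the test at that step were nitrogen uptake with 5 rises among 27 genes (median 0.12, but -0.10 with library totals alone), photosystem I, fatty acid synthesis with 2 falls among 14 and sigma factors with 1 rise among 5. Their adjusted p ran from 0.00107 to 0.0191, and adjusted p = 0.0535 to 0.897 with an estimated correlation. Fatty acid synthesis was lost there without t3_D of flask C (adjusted p = 0.0741) or t4_D of flask A (0.164), and sigma factors without flask A (0.105) or B (0.0598); the ranges over alternatives were 2.59e-05 to 0.897 and 4.36e-05 to 0.146. From t4_D to t5_D cobJ (MICAP_3615), of cobalamin synthesis, rose by 2.06 ± 0.30 and trxA (MICAP_2631) fell by 3.15 ± 0.61. ATP synthase had a median of -1.35 with no gene past the test singly (adjusted p = 3.13e-08, and adjusted p = 0.342 with an estimated correlation), and 9 further lists passed, with adjusted p = 0.324 to 0.865 with an estimated correlation. Of these, terminal oxidases rose (median 1.03) with no gene past the test singly. The others had falling medians, from -0.20 to -0.57: ribosomal proteins, oxidative stress defence, photosystem II, gas vesicles, fatty acid synthesis, glycogen synthesis, the phycobilisome and carbon fixation, with 1 gene each past the test in glycogen synthesis and oxidative stress defence and none in the rest. The calls for glycogen breakdown, ATP synthase, gas vesicles and fatty acid synthesis held without each flask and each single library, while the other 7 were lost without flask B and ribosomal proteins also without A. Without single libraries, photosystem II and terminal oxidases held, and the rest were lost without t5_D of flask A (adjusted p from 0.0917 for glycogen synthesis to 0.744 for ribosomal proteins). Without t4_D of flask C or t5_D of flask B, the phycobilisome (0.0558 and 0.144), carbon fixation (0.0521 and 0.13), ribosomal proteins (0.727, with a median of 0.066, and 0.204) and oxidative stress defence (0.206 and 0.204) were lost, the last also without 5 other libraries. Their ranges over alternatives were 2.24e-05 to 0.405 for glycogen synthesis, 5.41e-07 to 0.763 for the phycobilisome, 2.06e-14 to 0.763 for carbon fixation, 0.00012 to 0.865 for ribosomal proteins and 0.00483 to 0.324 for oxidative stress defence.

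Within the dark phase the microcystin genes fell. All 9 fell between t6_N and t7_N (median -1.62, adjusted p = 3.17e-09, and adjusted p = 0.557 with an estimated correlation), and from t7_N to t8_N the median was -1.19 with 1 of 9 past the test singly and 7 changed adjusted over the list alone (adjusted p = 5.48e-09, and adjusted p = 0.574 with an estimated correlation). Without flask B edgeR passed 6 genes in all from t6_N to t7_N. The 9 single calls at that step therefore did not all hold, while the list call did. mcyB (MICAP_2257) was at 143 ± 62.6 CPM at t6_N, 32.2 ± 14.4 at t7_N and 14.4 ± 5.47 at t8_N. The phosphoketolase gene xfp (MICAP_2729) fell by 2.34 ± 0.22 and pckA (MICAP_4008) rose by 2.11 ± 0.45 from t6_N to t7_N. Chaperones and proteases passed at both dark steps, with 7 rises and 1 fall among 27 genes and then 1 rise. Their medians were 0.42 and 0.28, but -0.00 and -0.03 with library totals alone, at adjusted p of 0.0174 and 0.0165 (adjusted p = 0.87 and 0.613 with an estimated correlation). At the last step clpC (MICAP_3158), a chaperone of the Clp protease, rose by 1.35 ± 0.28 and the purine synthesis gene purC (MICAP_0773) fell by 2.01 ± 0.37. Phosphate uptake passed at that step as well (median -0.49, adjusted p = 0.0435, and adjusted p = 0.66 with an estimated correlation). That call was lost without flask A or C or 3 of the single libraries, at adjusted p up to 0.204 without t7_N of flask C, and ranged from 0.00477 to 0.66 over alternatives. The chaperone call there was lost without flask B (adjusted p = 0.0641) or t8_N of flask C (0.147), with a range over alternatives of 0.000909 to 0.613.

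Fewer genes passed at the steps within a phase than at lights on. From t2_D to t3_D 606 genes passed (287 higher, 319 lower), from t3_D to t4_D 232 (194 higher, 38 lower), from t4_D to t5_D 76 (55 higher, 21 lower), from t6_N to t7_N 959 (461 higher, 498 lower) and from t7_N to t8_N 54 (34 higher, 20 lower). With library totals alone the shares higher were 26.0% at t3_D, 65.9% at t4_D, 9.30% at t7_N and 3.13% at t8_N, each against the time before, in place of 47.4%, 83.6%, 48.1% and 63.0%. With the flask as a term 997 genes passed for t3_D, 374 for t4_D, 184 for t5_D and 148 for t8_N. DESeq2 gave 152 for t5_D and 176 for t8_N. Without flask B edgeR passed 48 for t3_D, 53 for t4_D, 0 for t5_D (141 at an unadjusted p under 0.05), 6 for t7_N and 0 for t8_N (304 at an unadjusted p under 0.05). Without flask C 528 passed for t4_D and 265 for t5_D (90 higher, 175 lower, which turns the balance), and without flask A 287 for t3_D (202 higher, 85 lower, also turned), 85 for t4_D and 3 for t8_N. The t3_D balance also turned with DESeq2 size factors (317 higher, 250 lower), upper-quartile factors (308 and 250) and only the 6 libraries compared (656 and 614). DESeq2 turned it as well (388 and 330, and 559 and 514 with the flask as a term). In edgeR with the flask as a term it did not turn (436 and 561), nor with the other filters, with 1 gene per identical group or without the most abundant genes. For the step to t3_D, leaving out t2_D of flask B or C gave 331 or 284 genes and t3_D of flask A, B or C 401, 281 or 346. For the step to t4_D, t3_D of flask B or C gave 125 or 148 and t4_D of flask A 134. For t5_D, t4_D of flask C gave 44 and t5_D of flask B 38. For t7_N, t6_N of flask A gave 599 and t7_N of flask B 517. For t8_N, t7_N of flask A or C gave 11 or 129 and t8_N of flask B or C 18 or 34. Among the genes named for these steps, mcyC, hspA (MICAP_4533), ctaA, coxE and xfp held without each flask in turn; without flask B apcA had an adjusted p of 0.139 (range over alternatives 9.17e-09 to 0.139), hspA (MICAP_4174) 0.0513 (3.5e-11 to 0.0513), cobJ 0.149 (1.45e-12 to 0.149), trxA 0.555 (2.74e-09 to 0.555), pckA 0.16 (1.19e-05 to 0.16), clpC 0.525 (2.74e-06 to 0.547) and purC 0.467 (1e-05 to 0.547).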

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

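For the patterns below, the test for a swap of a flask C library, the tests of t8_N against t1_N without the most abundant genes and without flask C, and the genes and lists named for flask C were chosen after the result was seen.

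The change from day to night was compared between flasks. A test of that difference, night minus day in flask C against the other 2 flasks, passed 341 of 5157 genes in edgeR, 139 higher and 202 lower at night in flask C than in the others, with 1399 at an unadjusted p under 0.05. The same test passed 0 genes for flask A (760 at an unadjusted p under 0.05) and 0 for flask B (188); it was not run in DESeq2. Ribosomal protein genes made up part of the 341. Their difference was larger in flask C for 28 of 49, with a median of 0.80 (adjusted p = 9.28e-27, and adjusted p = 0.486 with an estimated correlation). Among them was rplC (MICAP_3862) with 1.65 ± 0.32 (SE, adjusted p = 0.0113). Of 10 ATP synthase genes 4 had a larger difference (median 1.18, adjusted p = 1.66e-07), and carbon fixation (median 0.98, adjusted p = 0.000107) and the phycobilisome (0.94, adjusted p = 0.000522) passed with no gene passing singly, each at adjusted p = 0.486 with an estimated correlation. The same lists passed for flask B in the other direction (camera): ribosomal proteins (adjusted p = 5.38e-14), ATP synthase (4.78e-05), phycobilisome (0.000327) and carbon fixation (0.000394). With an estimated correlation these were 0.586 to 0.632. For flask A only ribosomal proteins of these passed, also in that direction (0.0295, and 0.93 with an estimated correlation). Each test sets 1 flask against the other 2, so these tests are not independent. For the chaperonin genes groES (MICAP_0939) and groL (MICAP_0940) the night minus day difference was larger in flask C by 2.09 ± 0.53 and 2.05 ± 0.55 (adjusted p = 0.0293 and 0.0336), whereas the DNA repair gene uvrC (MICAP_4562) had -2.42 ± 0.39, clpB (MICAP_4822) -1.68 ± 0.28 and nrdB (MICAP_1382), for ribonucleotide reductase, -1.56 ± 0.28 (adjusted p = 0.00598, 0.00598 and 0.00863).

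At t7_N and t8_N the flask C libraries correlated better with the t1_N profile than with the profile of their own time, by 0.171 on average, against -0.201 in flask A and -0.184 in flask B. Library depth and a few genes taking most of the counts were argued against: the lead was 0.185 after thinning to 1 depth (0.182 to 0.189 over 5 draws), and at least 0.145 over 100 random draws of part of the genes without the RNA genes and the 10 most abundant genes. A swap of a flask C library with t1_N of flask C was argued against as well, since that library lay nearer t1_N than t7_N or t8_N by at least 0.165 over 100 such draws. In the light flask C did not lead: its t4_D and t5_D libraries matched the earlier times t3_D and t4_D best (0.827 and 0.705, and 0.770 and 0.655 with their own). A swap with a library outside the series, a difference in handling and a shift at night alone stay open; the flasks are replicates, so no biological explanation was tested.

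Between t8_N and t1_N, at the same clock hour, 422 genes passed in the fit of all libraries, and 1 with only the 6 libraries compared. Library depth was argued against, as thinning left 312 to 361 genes, and so was a small set of abundant genes, as 92.9% of the calls returned in the same direction without the RNA genes and the 10 most abundant genes. Flask C as the source of the calls was argued against by the 397 of the 422 that returned in the same direction without it; that 1305 genes (739 higher, 566 lower) then passed says no more, since the change over 24 h was smaller in flask C, with an SD over genes of 0.746 against 1.19 in flask A and 0.951 in flask B, and correlated less with the others (r = 0.282 and 0.299) than A with B (0.583); genes are not independent replicates. The calls were lost without either of the other flasks, as edgeR passed 0 genes without A (768 at an unadjusted p under 0.05) and 0 without B (570), and DESeq2, run with all libraries only, 542. Growth, the 150 mL drawn at each time and repeated handling of the same flasks go together with time in this design, and they stay open and untested.

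The mean TMM factor was 4.78 times as high at t2_D as at t1_N. The share of counts in RNA genes was argued against as the whole cause (ratio 4.76 without them), and so were library depth (4.70 after thinning) and the 10 most abundant genes (4.33, or 90.6% of the ratio). Removal of the 100 most abundant genes left a ratio of 2.49 (52.1%) and of the 500 most abundant 1.75 (36.7%), so a broad set of abundant transcripts carried part of it. Whether the amount of RNA per cell changed at lights on stays open, since library totals and TMM factors both give relative levels only.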

How the results depend on the processing

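Keeping 1 of each group of genes with identical counts, and the list tests for the 5 steps, were chosen after the data were seen. Most named results kept direction and side of the threshold. Over the settings other than omissions, 3574 of 3844 values for named genes did so, 114 fell short of the threshold, 120 newly passed and 36 reversed; for lists past the test 390 of 450 did so, 51 fell short and 9 reversed. With 1 flask left out 888 of 1056 values for genes and 136 of 150 for lists held, and with 1 library left out 8099 of 8448 and 1170 of 1200, with 1 list reversed. Depth limits the low end: a count of 0 allows up to 2.05 TMM-scaled CPM in the smallest library.

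With library totals alone, which leave composition uncorrected and so move the median of all genes, 2622 genes passed between t8_N and t1_N and 138 from t3_D to t4_D, 8 lists passed between light and dark, 10 at lights on and 3 at lights off, and 2887 genes peaked at t2_D. The reversals with this scaling were, between light and dark, gvpA MICAP_0577 0.73, MICAP_0575 0.62 and MICAP_0578 0.60, sasA 0.52, glgC 0.50, glgP (MICAP_2556) 0.11, cbbL 0.28, kaiB (MICAP_4307) 0.089, cpcA 0.21, isiB 0.22, rpoC (MICAP_1072) 0.29, rpoD (MICAP_5425) 0.36, photosystem I 0.14 and chaperones 0.085. At lights on they were sasA 1.98, mcyC 1.86, glgP 0.56 (MICAP_1326) and 0.046 (MICAP_2556), mcyF 0.39, atpB (MICAP_4772) 0.23, dnaK (MICAP_2646) 0.084, kaiB (MICAP_4307) 0.19, isiB 0.51, isiA 0.34, ndhF (MICAP_1083) 0.12, glnA 0.61, glnB (MICAP_3863) 0.13, msrB 0.69, psaK (MICAP_2211) 0.22, psbL 0.14, cpcD 0.22, rpoC (MICAP_1072) 1.57, rpoZ 0.19 and cytochrome b6f 0.36. Between t8_N and t1_N they were gvpA (MICAP_0575) 0.75, kaiA 0.72, cysS 0.032, glnA 0.12, psbD 0.028, photosystem II 0.028, cytochrome b6f 0.24 and NDH-1 0.29. For the steps they were nitrogen uptake -0.10 from t3_D to t4_D and chaperones -0.0043 from t6_N to t7_N and -0.028 from t7_N to t8_N.

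Upper-quartile factors passed 2 lists at lights off. Without the RNA genes and the 10 most abundant genes 3 lists passed between light and dark, with photosystem I and fatty acid synthesis lost. Oxidative stress defence from t4_D to t5_D was lost with at least 10 counts in every library of a group and with 1 gene kept per identical group. With an estimated correlation 0 lists passed between light and dark, 0 at lights on, 0 at lights off and 0 between t8_N and t1_N (camera), since that setting widens the null distribution by the correlation it estimates, and 3 of 50 list calls held. At an unadjusted p under 0.05 the numbers were 1, 2, 1 and 1. With fry, which tests each list by itself and not against the other genes, 22, 22, 1 and 0 lists passed in these 4 comparisons (23, 23, 3 and 7 at an unadjusted p under 0.05). At the 5 steps fry passed 8, 4, 1, 4 and 0 lists in order of time (5 at an unadjusted p under 0.05 at the last), where camera at the preset correlation passed 10, 6, 11, 2 and 3. DESeq2 passed 152 genes from t4_D to t5_D and 176 from t7_N to t8_N. Apart from the estimated correlation and fry, the cause was not tested for these.

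With only the 6 libraries compared, 180 genes passed at lights off, 1 between t8_N and t1_N, 1270 from t2_D to t3_D, 9 from t4_D to t5_D, 9 from t6_N to t7_N and 0 from t7_N to t8_N (edgeR, 316 at an unadjusted p under 0.05). The spread then rested on fewer libraries. The fit of all libraries shared 1 spread per gene over all times, but replicates differed unequally. Their chi-square per degree of freedom was 14.1 to 68.1 at t2_D and t3_D, and 51.9 to 414 at t6_N, t7_N and t8_N. A shared spread can therefore be too wide for the step from t2_D to t3_D and too narrow after lights off. Whether this gave the rise from t2_D to t3_D was not tested.

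With the flask as a term (a block for the pairing), 791 genes passed between t8_N and t1_N, 997 from t2_D to t3_D, 374 from t3_D to t4_D, 184 from t4_D to t5_D and 148 from t7_N to t8_N, and 5 lists at lights on and 2 at lights off. DESeq2 with the block passed 1137 genes at lights off, 1042 between t8_N and t1_N, 1073 from t2_D to t3_D, 501 from t3_D to t4_D, 237 from t4_D to t5_D, 1550 from t6_N to t7_N and 330 from t7_N to t8_N, with 1034 opposite calls. In edgeR 24 genes of the naming rule newly passed with the block, at lights off or between t8_N and t1_N, as did NDH-1 and phosphate uptake between light and dark and the other natural products between t8_N and t1_N. The block changed no other call of a named gene and took no list below the threshold; at the 5 steps it was compared only for lists already past the test. The block raised the count of genes in both tools in each comparison: between t8_N and t1_N from 422 to 791 in edgeR and from 542 to 1042 in DESeq2, at lights off from 690 to 1011 and from 866 to 1137, and for opposite calls from 645 to 920 and from 800 to 1034. Within a flask the residuals of t8_N and t1_N correlated at 0.0017 to 0.0598. The rise between these 2 times therefore cannot be read as a gain from pairing their libraries.

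Omission of each flask or library gave 2934 (without flask B) to 4387 genes (without t6_N of C) across the 8 times, 3530 (B) to 4093 (t6_N of C) between light and dark, 2949 (B) to 3815 (t6_N of C) at lights on, 3 (B) to 807 (t7_N of C) at lights off and 0 (A or B) to 1305 (C) between t8_N and t1_N. The steps gave 48 (B) to 687 (t6_N of C), 53 (B) to 528 (C), 0 (B) to 265 (C), 6 (B) to 1206 (t7_N of A) and 0 (B) to 129 (t7_N of C), in order of time. The counts of 0 came from edgeR, with 768 genes without A and 570 without B between t8_N and t1_N, 141 at t5_D and 304 at t8_N at an unadjusted p under 0.05; DESeq2 was not run on these subsets. Lists past the test ran from 4 (without t6_N of A) to 8 (C), from 3 to 5 (C), from 1 to 5 (t6_N of C) and from 8 (t1_N of C) to 12 (C) for light against dark, lights on, lights off and t8_N against t1_N. Opposite calls ran from 3 (B) to 746 (t7_N of C) and genes highest at t2_D from 842 (C) to 1461 (t2_D of A). From t4_D to t5_D the median of the ribosomal protein list ran from -0.51 (without t5_D of C) to 0.066 (without t4_D of C), a reversal. Each omission leaves fewer libraries, which lowers the power. Without flask B the flasks left were A and C, the pair that differed most from t4_D to t8_N. Their chi-square per degree of freedom was 283 to 414 at these times. Whether this is why most counts fell furthest without flask B was not tested.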

Other observations

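With TMM factors and all libraries, the lists not described so far gave no adjusted p under 0.05 between light and dark, and several split. Of 3 terminal oxidase genes 2 fell in the light (median -2.09, adjusted p = 0.175), such as coxA (MICAP_5408) with -2.09 ± 0.15 (SE, n = 12 and 12), and 5 of 6 iron homeostasis genes fell while 1 rose (median -1.15, adjusted p = 0.175). Sigma factors had 3 falls and 1 rise among 5 genes (median -0.72, but 0.36 with library totals alone, adjusted p = 0.334), with sigB (MICAP_4957) at -2.33 ± 0.17. Glycogen synthesis had 2 rises and 1 fall among 4 (adjusted p = 0.264, but 0.0364 with library totals alone, range over alternatives 0.0364 to 0.855). Cell division had 5 rises and 1 fall among 8 (median 0.50, adjusted p = 0.334), with sepF (MICAP_5176) at 2.04 ± 0.15, and aminoacyl-tRNA synthetases 13 rises and 7 falls among 21 (adjusted p = 0.363), from ileS (MICAP_1068) with 1.82 ± 0.12 to cysS (MICAP_1830) with -1.91 ± 0.10.

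Other lists went both ways. Nitrogen uptake had 9 rises and 12 falls among 27 genes, chlorophyll synthesis 6 and 5 among 12, oxidative stress defence 5 and 5 among 11 and pili 5 and 3 among 8, with a median of 0.43 but a mean of -0.21 for pili, and an adjusted p of 0.677 for each of these 4. Within them glnB (MICAP_5301) rose by 4.47 ± 0.28 and chlG (MICAP_3387) by 3.82 ± 0.24, whereas dps (MICAP_5465), which protects DNA, had -1.45 ± 0.14. Cytochrome b6f and mobile carriers had 6 falls among 10 (median -0.61, but 0.54 with library totals alone, adjusted p = 0.175), carbon fixation 5 rises and 5 falls among 13 (median -0.45, but 0.79 with library totals alone, mean 0.23, adjusted p = 0.577), ATP synthase 4 rises among 10 (adjusted p = 0.677, but 0.0146 without flask C, range over alternatives 0.0146 to 0.944) and the RNA polymerase core 2 falls among 5 (median -0.31, but 0.86 with library totals alone, adjusted p = 0.577). The phycobilisome had 2 rises and 5 falls among 12, photosystem II 5 and 5 among 17, DNA replication 6 and 4 among 12 and ribosomal proteins 9 and 17 among 49, with adjusted p of 0.771, 0.797, 0.794 and 0.967; with library totals alone the medians of phycobilisome, photosystem II and ribosomal proteins turned from -0.19, -0.074 and -0.30 to 1.02, 1.03 and 0.88. A p that misses the threshold does not show that levels were equal.

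Chance was tested by splitting the libraries in other ways. A free assignment of the time labels to the libraries was argued against for the genes changed across the 8 times (4237, highest of the other splits 2168). The same held between light and dark (4060 against 1950). In both, 1 of 100 splits, the real one, gave as many. These splits ignored the flask and the order of sampling, so they do not exclude flask structure or drift over time. For the genes highest at t2_D (1303, and 873 at 1 time in the highest other split, with 1 of 100 as large) the splits decide nothing, because 5 of the other splits had any changed gene to count. As a share, 30.8% of the changed genes were highest at 1 time in the real split, and 40.3% and 52.1% in the 2 other splits with more than 2 changed genes. For the opposite calls at the light transitions (645, and 19 in the highest other split, with 1 of 200 as large) they decide nothing either, because 1 other split had calls at both transitions, the real one with the direction at lights off turned round. Chance cannot be excluded for the number of lists past the test between light and dark, as 57 of 100 splits gave as many as the real 5 and the highest gave 15.

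For each pair of times the 10 splits are too few for a share under 0.05. At lights on 3744 genes passed and 0 in the highest other split, at lights off 690 and 0, between t8_N and t1_N 422 and 0 (each the largest of its 10). From t2_D to t3_D the values were 606 and 0, from t3_D to t4_D 232 and 1, from t4_D to t5_D 76 and 28 and from t6_N to t7_N 959 and 927, with 1 split of 10 as large in each, the real one. From t7_N to t8_N 54 genes passed and 543 in the highest other split (2 of 10 as large). That split put t8_N of flask A and t7_N of flasks A and B against t7_N of flask C and t8_N of flasks B and C, and the one with 927 genes put t7_N of A and t6_N of A and B against t6_N of C and t7_N of B and C. Both part 1 flask pair and set flask C apart from flask A, which points to a structure of the samples by flask. The 3 other splits that part all 3 flask pairs, as the real one does, gave 0 genes for each of the 8 pairs of times in edgeR. For lists past the test the values were 3 at lights on and 7 in the highest other split (10 of 10 as large), 1 and 17 at lights off (9 of 10) and 9 and 12 between t8_N and t1_N (4 of 10), again too few splits for a share under 0.05.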
